A study of Mus musculus with 24 samples.

How the data were processed

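Expression was measured in ear skin of 24 mice on Illumina bead arrays with biotin-labelled cRNA. The series design describes separate animals per sample, 3 naive mice per strain and 4 or 5 per infection, aged 6 to 8 weeks and sampled 4 weeks after infection. The labels name the source as ear with lesion even for naive mice, and the groups were taken from the infection and strain given for each sample. The deposited table holds, as intensity, the mean bead signal of 25697 probes on each array, not normalized between arrays. Beside each signal the deposited table gives, per the file headers, a detection p-value, which fell with rising signal on every array. The authors' series matrix also holds intensity, on a linear scale with array medians between 335.1 and 335.9. Each of its columns equalled the quantile-normalized signal of its array within 0.0498 log2 units, and it was used only as an alternative. GenomeStudio 1.8 is named per the submitters' processing notes, and they do not state whether background was subtracted.

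The signals were corrected with limma 3.58.1 in R 4.3.3 by neqc (normexp background from the detection p-values, offset 16, quantile normalization, log2). Of the 25697 probes 23978 name 1 gene, 0 several and 1719 none. A probe was kept with a detection p under 0.01 on at least 3 arrays, which 13963 did, 13132 of them with a gene. Where a gene had several such probes (2408 genes) the one with the highest mean was used, leaving 9931 genes. Detected probes without a gene (831) were tested apart. Array signal over background sets what can be seen, and 41.4% to 49.9% of probes were detected per array.

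A limma model with a mean for each of the 6 groups gave 13 comparisons. These were each infection against the naive ears of its strain, the strains under each infection and naive, the parasites within each strain, the susceptible group against the mean of the 3 resistant ones, and 3 interactions. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, 2-sided, within a comparison. Changes are log2 fold changes with limma's standard error. Where a gene was not well above background on any array of 1 group, its change is given as at least N-fold. That bound is the mean of the brighter group minus the mean of the dimmer group's values, each raised to the lowest normalized signal among detected probes of its array. In contrasts of more groups such a group stands at that floor.

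The text names genes by a rule. It admits the 6 largest rises and falls among genes that passed without overlap between groups (the 4 largest of each sign for interactions), the 2 largest of each sign in each gene list, a set of sentinel cytokine and effector genes, and genes named for another comparison. Unnamed clones and predicted genes were skipped, and the text leaves out some genes that the rule admits. The comparisons, lists, rule and the main other settings were fixed before the data were examined. The 34 gene lists cover cytokines, interferon responses, leukocyte classes, skin and ear tissues, matrix, metabolism and technical markers. Each was tested by camera with a preset correlation of 0.01, adjusted over the 34 lists, then with an estimated correlation, and by fry. Of the lists called in BALB/c L. major ears against naive ones, 10 held with an estimated correlation, as did 7 in each of the other infections and 3 in B6 L. major against L. braziliensis ears (adjusted p = 0.042 each), and 0 in the other comparisons. A list score is the mean log2 of the measured members, centred on the mean of all arrays, and scores were compared by exact permutation tests, 2-sided.

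Slides were read from array identifiers. Each comparison was refitted with slide as a fixed block, as a random one (correlation within slides 0.479), and within each slide holding both groups. Other alternatives were no background correction, median in place of quantile scaling, the series matrix, other filters, probe rules, thresholds and variance models, array weights, only the groups compared, a block by replicate number, and leaving out each array in turn.

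Simulated data had 200 of 9931 genes changed in each comparison. Between 1 and 132 were found at 1.5-fold, 80 to 180 at 2-fold and 175 to 200 at 4-fold, the fewest in the interactions, and 0 in the wrong direction. False calls made up 0% to 16.7%, 3.2% to 10.8% and 2.1% to 8.5% of calls. A simulated slide shift gave up to 1853 false calls without a slide block (the main model) and up to 14 with it. A list of 25 members raised 1.5-fold was called in 13 of 13 comparisons, and 0 of 1300 other list tests passed. This does not show how lists of genes that vary together fare. Summaries and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.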

Results

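Whole-ear RNA from 24 mice was read on Illumina expression bead arrays, 1 array per mouse. The ears came from BALB/c and C57BL/6 (B6) mice that were naive or had been infected for 4 weeks with Leishmania major or Leishmania braziliensis, protozoan parasites that live in macrophages. There were 3 naive BALB/c and 3 naive B6 ears, 5 BALB/c and 4 B6 ears with L. major, and 4 BALB/c and 5 B6 ears with L. braziliensis. The labels call BALB/c mice with L. major susceptible and the other 3 infected groups resistant, and the series title sets lesions that do not heal against lesions that do. An array detected between 10635 and 12818 of its 25697 probes, and its median signal before normalization lay between 250.2 and 443. After filtering, 9931 genes were tested. The number of arrays per group limits the precision.

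The arrays were run on 3 slides of 8. Slide 1 held the 6 naive ears and BALB/c L. major replicates 1 and 2. Slide 2 held BALB/c L. major replicates 3, 4 and 5, the 4 BALB/c L. braziliensis ears and B6 L. major replicate 1. Slide 3 held B6 L. major replicates 2, 3 and 4 and the 5 B6 L. braziliensis ears. B6 and BALB/c ears with L. braziliensis never shared a slide with their naive controls or with each other. B6 L. major replicate 1 alone links slide 3 to the other slides, so a value with slide as a block that sets infected B6 ears against naive or BALB/c ears rests on that array.

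The first principal component (45.8% of the variance) ran from naive to infected ears and the second (25%) parted the strains. On the first, naive ears scored between -64.4 and -54.7, B6 L. braziliensis ears between -21.5 and -6.06, B6 L. major ears between 1.78 and 38.4, and BALB/c infected ears between 6.95 and 56.2. On the third (5.51%), BALB/c L. major replicates 1 and 2 on slide 1 scored 34.0 and 29.2, while replicates 3, 4 and 5 on slide 2 scored -4.79, 6.16 and -9.31. BALB/c L. major replicates 3 and 5 had a higher median correlation with the arrays of another group than with their own (0.978 against 0.975, and 0.976 against 0.963), as did B6 L. major replicate 2 (0.977 against 0.976).

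**Figure D1:**
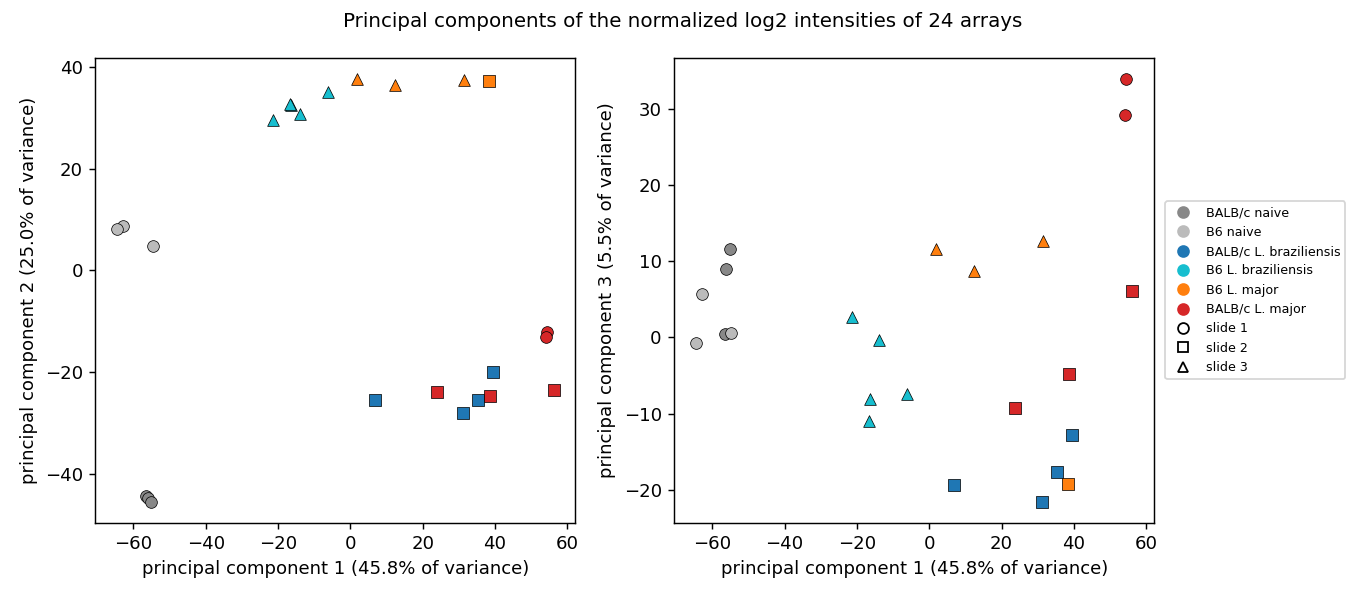
Principal components of the normalized log2 intensities of 24 arrays, each point an array, coloured by group and shaped by slide, with the share of variance on each axis in percent. Naive ears lie at -54.7 or lower on the first component, and all BALB/c infected ears lie at 6.95 or higher.

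What L. major did to the ear of the susceptible strain was asked by setting 5 BALB/c ears with L. major against 3 naive BALB/c ears. Ccl4, a chemokine for macrophages and T cells, rose at least 289-fold (adjusted p = 2.53e-11), and Fpr2, a formyl peptide receptor of neutrophils and macrophages, at least 216-fold (adjusted p = 1.73e-15). Cxcl9, which interferon-gamma induces, rose at least 175-fold (adjusted p = 1.94e-15), the acute-phase gene Saa3 at least 118-fold (adjusted p = 3.11e-14), and F10, coagulation factor X, at least 102-fold (adjusted p = 1.17e-13). The Fc receptor gene Fcgr4 (Entrez 246256, chromosome 1) rose by 7.42 ± 0.20 (log2 fold change ± SE, adjusted p = 9.58e-17). Inmt fell by 2.86 ± 0.52, with Abca8a at -2.83 ± 0.41 and the small leucine-rich proteoglycan gene Omd at -2.80 ± 0.31. For every gene named in this comparison all 5 infected ears lay beyond all 3 naive ears.

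In all, 4998 of 9931 genes passed limma's test (adjusted p under 0.05), 1930 higher and 3068 lower, and 2022 of them changed at least 2-fold. In 4178 of them, and in 45.7% of all genes, the groups did not overlap (by chance 3.57%). With slide as a block 5036 genes passed, 4219 of them among the 4998 and in the same direction. Within slide 1, 2 infected against 3 naive ears gave 5060.

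All 25 measured interferon-gamma-inducible genes rose, also 25 adjusted over the list alone (camera adjusted p = 1.62e-28). They included Cxcl10 (at least 45.1-fold), Cd274, which encodes the inhibitory ligand PD-L1 (4.52 ± 0.20), and Nos2, the inducible nitric oxide synthase that kills parasites in macrophages (at least 7.13-fold, adjusted p = 6.7e-09). Of 21 measured type I interferon-inducible genes 20 rose and 1 fell, the same numbers adjusted over the list alone (adjusted p = 1.18e-16), with Isg15 up by 5.71 ± 0.37. Of 14 type 1 cytokine and receptor genes 9 rose, 9 adjusted over the list alone (adjusted p = 1.08e-06). Among them were Ifng (at least 6.33-fold, adjusted p = 2.33e-11), Tnf (at least 12.3-fold) and the interleukin-12 signal transducer Stat4 (at least 10.7-fold).

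Of 7 measured type 2 cytokine and chemokine genes 4 rose and 1 fell, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.0618). Within it Il4, the hallmark cytokine of type 2 helper cells, rose at least 9.74-fold (adjusted p = 5.07e-06). Of 19 alternatively activated macrophage genes 11 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.000108, adjusted p = 0.19 with an estimated correlation). Arg1, the arginase that competes with Nos2 for arginine, rose by 7.12 ± 0.53 and the chitinase-like Chil3 at least 36.4-fold, while the scavenger receptor gene Cd36 fell by 1.69 ± 0.33. Il10, which restrains macrophage activation, rose at least 5.21-fold (adjusted p = 9.37e-08), and Foxp3, the regulator of regulatory T cells, by 2.33 ± 0.21. They belong to 18 regulatory T cell and inhibitory genes, of which 14 rose and 1 fell, 15 and 1 adjusted over the list alone (adjusted p = 9.77e-10).

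Of 29 monocyte and macrophage genes 27 rose, 27 adjusted over the list alone (adjusted p = 7.93e-25). Of 21 neutrophil genes 18 rose and 1 fell, the same adjusted over the list alone (adjusted p = 1.83e-11, adjusted p = 0.0606 with an estimated correlation). The alarmin S100a8 rose by 5.60 ± 0.61, and Mpo, the myeloperoxidase of neutrophil granules, fell by 1.65 ± 0.33. Of 21 genes of interleukin-1, the inflammasome and neutrophil attraction, the interleukin-1 list, 19 rose, 19 adjusted over the list alone (adjusted p = 2.92e-14), with Il1b up by 7.63 ± 0.49 and the neutrophil chemokine Cxcl2 at least 119-fold.

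Among lymphocyte lists, 13 of 17 T cell genes rose, 13 adjusted over the list alone (adjusted p = 1.81e-10), with the T cell receptor subunit Cd3d up by 3.45 ± 0.27. Of 16 cytotoxic lymphocyte genes 13 rose, 13 adjusted over the list alone (adjusted p = 1.94e-09), with Nkg7 of cytotoxic granules up by 4.36 ± 0.29 and the chemokine Ccl5 at least 57.9-fold. Of 12 B cell and plasma cell genes 7 rose and 1 fell, 8 and 1 adjusted over the list alone (adjusted p = 0.00328, adjusted p = 0.0857 with an estimated correlation). Fcrla of B cells rose at least 4.33-fold and the B cell kinase gene Blk fell at least 1.23-fold. Of 21 dendritic cell and MHC class II genes 16 rose and 1 fell, the same adjusted over the list alone (adjusted p = 4.94e-11), with the costimulatory receptor Cd40 up by 4.30 ± 0.18. Of 12 mast cell, basophil and eosinophil genes 6 rose and 2 fell, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.115). There the eosinophil granule gene Prg2 rose at least 3.07-fold and the mast cell receptor gene Mrgprb2 fell by 0.90 ± 0.23. Of 14 complement genes 7 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.000683), with complement factor B, Cfb, up by 3.05 ± 0.21 and the complement inhibitor Cd59a at -1.34 ± 0.21.

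Of 30 wound and stress keratinocyte genes 23 rose and 1 fell, 25 and 1 adjusted over the list alone (adjusted p = 2.18e-09, adjusted p = 0.208 with an estimated correlation). The keratin of regenerating epidermis Krt16 rose by 5.58 ± 0.65 and the cornified envelope gene Sprr2e by 5.63 ± 0.82. Of 35 keratinocyte differentiation genes 2 rose and 7 fell, 2 and 3 adjusted over the list alone, and the list did not pass (adjusted p = 0.764). Krt1 of the suprabasal layers rose by 1.27 ± 0.32 and the basal keratin Krt15 fell by 2.03 ± 0.25. Of 21 hair follicle genes 1 fell, and 0 did adjusted over the list alone, with 1 at unadjusted p under 0.05 in limma (adjusted p = 0.764). Of 20 sebaceous gland and skin lipid genes 14 fell and 2 rose, the same adjusted over the list alone (adjusted p = 0.00822, adjusted p = 0.292 with an estimated correlation). Cyp2e1 of lipid oxidation fell by 2.33 ± 0.53, and the lipoxygenase gene Alox8, which stands in that list but oxidizes arachidonic acid, rose at least 7.50-fold.

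Among lists of resident tissue, 31 of 33 skeletal muscle genes fell, 31 adjusted over the list alone (adjusted p = 4.42e-06, adjusted p = 0.405 with an estimated correlation), with the fast myosin Myh4 at -2.55 ± 0.57 and the muscle creatine kinase Ckm at -2.17 ± 0.47. Of 15 cartilage genes 14 fell, 14 adjusted over the list alone (adjusted p = 2.41e-06, adjusted p = 0.19 with an estimated correlation), with Cytl1 at -2.55 ± 0.29 and Ucma at -2.22 ± 0.31. Of 22 adipocyte genes 16 fell, 16 adjusted over the list alone (adjusted p = 5.25e-05, adjusted p = 0.269 with an estimated correlation), with Car3 at -2.18 ± 0.51. Of 7 melanocyte genes 5 fell, 5 adjusted over the list alone (adjusted p = 0.00794, adjusted p = 0.19 with an estimated correlation), with Tyrp1 of melanin synthesis at -2.33 ± 0.29. Of 11 nerve and Schwann cell genes 8 fell and 1 rose, 8 and 2 adjusted over the list alone (adjusted p = 0.0448, adjusted p = 0.295 with an estimated correlation). The myelin gene Mbp fell by 1.98 ± 0.34, and Mag, also of myelin, rose by 1.09 ± 0.22.

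Of 17 matrix metalloproteinases and inhibitors 12 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.000564, adjusted p = 0.196 with an estimated correlation). The collagenase Mmp13 rose by 6.02 ± 1.03 and the macrophage elastase Mmp12 at least 23.6-fold, while the inhibitor Timp3 fell by 1.58 ± 0.23. Of 24 fibrillar collagen and matrix genes 13 fell and 5 rose, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.123). Elastin, Eln, fell by 1.36 ± 0.15 and the fibroblast protease gene Fap fell by 1.73 ± 0.30, while Inhba, a subunit of activin A and not a matrix protein, rose by 3.56 ± 0.56. Of 26 endothelial and lymphatic genes 9 rose and 4 fell, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.0836), with the adhesion gene Icam1 up by 1.81 ± 0.15 and the angiopoietin receptor Tek at -0.99 ± 0.20.

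Of 25 hypoxia and glycolysis genes 16 rose and 1 fell, 17 and 1 adjusted over the list alone (adjusted p = 1.72e-05, adjusted p = 0.177 with an estimated correlation). Hk3, the hexokinase of myeloid cells, rose by 6.57 ± 0.22. Of 29 cell cycle genes 13 rose and 1 fell, the same adjusted over the list alone and 5 and 1 with median scaling (adjusted p = 0.00172, adjusted p = 0.409 with an estimated correlation), with the mitotic gene Birc5 up by 0.90 ± 0.24. Of 39 mitochondrial respiration genes 23 fell, 25 adjusted over the list alone (adjusted p = 0.000273, adjusted p = 0.19 with an estimated correlation). Of 33 ribosomal protein genes 13 fell, 12 adjusted over the list alone (adjusted p = 0.0265, adjusted p = 0.269 with an estimated correlation), with Rpl22 at -0.85 ± 0.14. Of 22 immediate early and heat shock genes 9 rose and 4 fell, 10 and 4 adjusted over the list alone, and the list did not pass (adjusted p = 0.0654), with the stress gene Atf3 up by 3.34 ± 0.29 and the heat shock gene Hspb1 at -0.86 ± 0.24. Of 4 measured erythrocyte genes 1 fell, 1 adjusted over the list alone (adjusted p = 0.309), and of 2 measured sex-linked markers 1 fell, 1 adjusted over the list alone (adjusted p = 0.425). With slide as a block ribosomal and nerve lists no longer passed (adjusted p = 0.111 and 0.0506), and within slide 1 ribosomal and melanocyte lists did not (adjusted p = 0.158 and 0.0514). Across the settings tried, the p of the ribosomal list ran up to 0.887, with median scaling.

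The same parasite was read in the resistant strain by setting 4 B6 ears with L. major against 3 naive B6 ears. Fpr2 rose at least 165-fold (adjusted p = 2.53e-15), the chemokine Ccl5 at least 81.3-fold (adjusted p = 2.5e-11) and Cxcl10 at least 68.9-fold (adjusted p = 4.06e-15). Fcgr4 rose by 8.15 ± 0.21 (adjusted p = 1.71e-17), Saa3 by 7.39 ± 0.33 and Cxcl9 by 7.25 ± 0.30. The natural killer receptor gene Klra7 (Entrez 16638, chromosome 6) rose at least 21.5-fold (adjusted p = 1.47e-17). The muscle gene Sln fell by 2.64 ± 0.42, with Ces1f at -2.58 ± 0.36, Fap at -2.28 ± 0.32 and the adipocyte hormone Adipoq at -2.17 ± 0.29. All 4 infected ears lay beyond all 3 naive ears for every gene named in this comparison except S100a8.

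Limma passed 4280 genes, 1763 higher and 2517 lower, and 1658 of them changed at least 2-fold (859 higher, 799 lower). In 3893 of them, and in 47% of all genes, the groups did not overlap (by chance 5.71%). A block for slide gave 3828, 2802 of them shared with the 4280 in direction. With arrays scaled to a common median in place of quantiles, 59.1% of calls were higher rather than 41.2%, and the median gene moved from -0.11 to 0.04.

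All 25 interferon-gamma-inducible genes rose, 25 adjusted over the list alone (adjusted p = 7.12e-32), and all 29 monocyte and macrophage genes rose, 29 adjusted over the list alone (adjusted p = 1.32e-27). The complement gene C1qb rose by 2.98 ± 0.17, Ifng at least 11.7-fold (adjusted p = 1.8e-11), Isg15 at least 23.8-fold and Nos2 at least 6.10-fold (adjusted p = 2.17e-08). Of 21 neutrophil genes 12 rose, 12 adjusted over the list alone (adjusted p = 1.78e-06, adjusted p = 0.235 with an estimated correlation). The C-type lectin gene Clec4e rose at least 24.7-fold, but S100a8 did not pass (0.75 ± 0.63, adjusted p = 0.358). Of 21 interleukin-1 list genes 13 rose, 15 adjusted over the list alone (adjusted p = 1.04e-07, adjusted p = 0.198 with an estimated correlation), with Il1b up by 4.51 ± 0.52 and Ccl4 by 5.37 ± 0.58. Tnf rose by 3.01 ± 0.34, Arg1 by 4.95 ± 0.56, Il4 at least 4.97-fold (adjusted p = 0.000534) and Il10 at least 3.19-fold (adjusted p = 4.85e-06).

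Of 30 wound and stress keratinocyte genes 13 rose, 13 adjusted over the list alone (adjusted p = 4.99e-05), with the wound keratin Krt6b up by 4.74 ± 0.72. Of 33 skeletal muscle genes 24 fell, 27 adjusted over the list alone (adjusted p = 1.92e-06), with Myh4 at -2.18 ± 0.59. Of 15 cartilage genes 12 fell, 13 adjusted over the list alone (adjusted p = 7.26e-05), with Ucma at -2.32 ± 0.33 and Mia at -2.02 ± 0.28. These had adjusted p = 0.408, 0.408 and 0.313 with an estimated correlation. Each of these 7 lists still passed with slide as a block.

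For L. braziliensis in BALB/c mice, 4 infected ears were set against the 3 naive ones. Cxcl9 rose at least 177-fold (adjusted p = 9.42e-15), Ccl4 at least 149-fold (adjusted p = 6.71e-10), Saa3 at least 79.9-fold (adjusted p = 3.55e-13) and Fpr2 at least 76.5-fold (adjusted p = 7.93e-14). Fcgr4 rose by 7.16 ± 0.21 and Il1b by 6.48 ± 0.52. Il4 rose at least 14.1-fold (adjusted p = 2.89e-06), Ifng at least 7.35-fold (adjusted p = 4.45e-11), Stat4 at least 12.0-fold and Il10 at least 4.97-fold. The myosin gene Myh1 fell by 3.12 ± 0.47 and the myoglobin gene Mb fell by 2.73 ± 0.40, and the amino acid transporter gene Slc7a10 fell by 2.71 ± 0.32. All 4 infected ears lay beyond all 3 naive ears for each of the genes named in this comparison.

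Limma passed 4063 genes, 1839 higher and 2224 lower, and 1634 of them changed at least 2-fold. In 3830 of them, and in 50.1% of all genes, the groups did not overlap (by chance 5.71%). With slide as a block 3198 passed, 2351 of them shared with the 4063 in direction.

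All 25 interferon-gamma-inducible genes rose, 25 adjusted over the list alone (adjusted p = 1.2e-28), with Cxcl10 up at least 43-fold. Of 29 monocyte and macrophage genes 27 rose, 27 adjusted over the list alone (adjusted p = 1.89e-23). Of 21 neutrophil genes 16 rose and 1 fell, the same adjusted over the list alone (adjusted p = 9.83e-09, adjusted p = 0.134 with an estimated correlation), with S100a8 up by 4.25 ± 0.63. Of 21 interleukin-1 list genes 18 rose, 18 adjusted over the list alone (adjusted p = 4.41e-11, adjusted p = 0.0789 with an estimated correlation). Of 29 cell cycle genes 22 rose, 22 adjusted over the list alone (adjusted p = 1.21e-06, adjusted p = 0.267 with an estimated correlation), with Top2a of dividing cells up by 1.21 ± 0.20 and Birc5 by 1.28 ± 0.25. Of 12 mast cell, basophil and eosinophil genes 7 rose, 7 adjusted over the list alone (adjusted p = 0.000775, adjusted p = 0.139 with an estimated correlation), and Rnase2a, of the eosinophil ribonuclease family, rose by 5.62 ± 1.0. Of 33 skeletal muscle genes 32 fell, 33 adjusted over the list alone (adjusted p = 6.92e-10, adjusted p = 0.305 with an estimated correlation). Arg1 rose by 6.29 ± 0.56, Tnf at least 9.41-fold, Nkg7 by 4.96 ± 0.31 and Krt16 by 4.92 ± 0.68. The adipocyte gene Plin1 fell by 1.97 ± 0.37, with Cidec at -1.89 ± 0.32, the cartilage regulator Sox9 at -1.97 ± 0.25 and Fap at -2.10 ± 0.32. Each of these 7 lists still passed with slide as a block.

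Fewest genes changed in B6 mice with L. braziliensis, 5 infected against 3 naive ears. Fcgr4 rose by 7.19 ± 0.20 (adjusted p = 9.31e-17), Cxcl9 by 6.40 ± 0.28 and Saa3 by 5.75 ± 0.32. The interferon-induced GTPase gene Gbp2b rose at least 43.1-fold (adjusted p = 3.16e-09), Fpr2 at least 39.8-fold (adjusted p = 2.46e-13), Ccl5 at least 34.7-fold (adjusted p = 5.51e-10), Cxcl10 at least 25.9-fold, Klra7 at least 15-fold (adjusted p = 3.8e-17) and Ifng at least 6.11-fold (adjusted p = 6.36e-10). Il1b rose by 2.73 ± 0.49, Arg1 by 3.37 ± 0.53, Ccl4 by 3.50 ± 0.55 and Tnf by 1.68 ± 0.33. The imprinted gene Peg3 fell at least 1.54-fold, the nuclear receptor gene Nr2f2 at least 1.73-fold, with Gng13 at -2.06 ± 0.45, Krt15 at -1.02 ± 0.25 and Col1a2 at -0.97 ± 0.16. All 5 infected ears lay beyond all 3 naive ears for every gene named in this comparison.

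Limma passed 1689 genes, 950 higher and 739 lower, and 593 of them changed at least 2-fold (453 higher, 140 lower). In 1585 of them, and in 29.7% of all genes, the groups did not overlap (by chance 3.57%). Without B6 naive replicate 2 the count was 942 and without replicate 3 it was 1048. A block for slide gave 2354, 993 of them shared with the 1689 in direction. With median scaling 87.9% of calls were higher rather than 56.2%, and the median gene moved from -0.05 to 0.17.

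All 25 interferon-gamma-inducible genes rose, 25 adjusted over the list alone (adjusted p = 8.81e-44), with Cd274 up by 2.87 ± 0.20. Of 29 monocyte and macrophage genes 26 rose, 27 adjusted over the list alone (adjusted p = 4.36e-33). C1qb rose by 2.29 ± 0.17, Cd40 by 2.54 ± 0.18, Hk3 by 4.71 ± 0.22 and Isg15 at least 7.83-fold. Of 16 cytotoxic lymphocyte genes 13 rose and 1 fell, the same adjusted over the list alone (adjusted p = 1.82e-12), the fall being that of perforin, Prf1 (-0.66 ± 0.17, adjusted p = 0.00969), which turned to 0.28 (adjusted p = 0.367) with the mean of its probes. Of 21 neutrophil genes 6 rose, 8 with 1 fall adjusted over the list alone (adjusted p = 1.11e-05). Of 21 interleukin-1 list genes 8 rose, 9 adjusted over the list alone (adjusted p = 1.95e-05). Both had adjusted p = 0.27 with an estimated correlation. Of 33 skeletal muscle genes 0 passed limma's test either way, 0 adjusted over the list alone (adjusted p = 0.788), with 1 at unadjusted p under 0.05. Blocked by slide, 12 of the 33 fell and that list passed (adjusted p = 4.84e-07), while its median turned from -0.07 to 0.17 with arrays scaled to a common median.

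Across the 4 infections 1094 genes passed in the same direction in each, 728 higher and 366 lower. Independent calls would give 6.07 and 13. Simulations of the same arrays without change (100, shared controls included) gave 0, but without responses cannot test the overlap. The 2 infections of a strain shared 3 naive ears that cannot be split, so part of the excess may come from them. In BALB/c the changes had a covariance over genes of 0.916, against 0.0384 in simulations, and in B6 0.510 against 0.0385. In BALB/c 1443 genes were higher in both infections (357 expected) and 1840 lower in both (687 expected), and in B6 917 (169 expected) and 643 (187 expected). Without B6 naive replicate 2 the 1094 fell to 680.

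**Figure D2:**
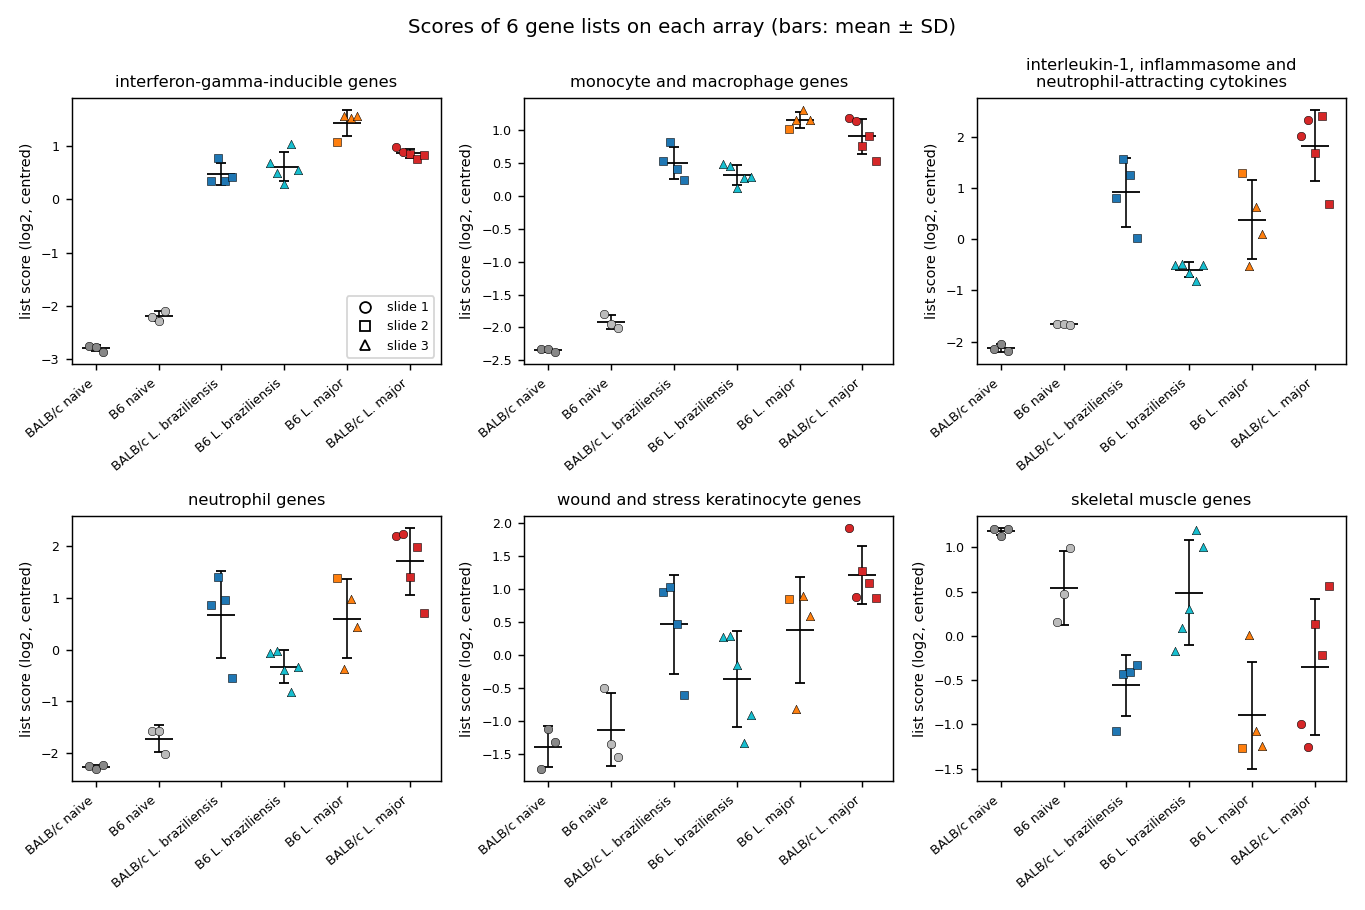
Scores of 6 gene lists on each array (the mean log2 intensity of a list's measured members, centred over arrays), by group, each point an array shaped by slide and each bar the group mean with its SD. The interferon-gamma-inducible score averages 1.43 in B6 L. major ears and -2.19 in naive B6 ears, and the interleukin-1 score averages 1.83 in BALB/c L. major ears and 0.38 in B6 L. major ears.

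What marks the susceptible mice among the infected was asked by setting the 5 BALB/c L. major ears against the mean of the 3 resistant groups (13 ears). Il12a, a subunit of interleukin-12 and interleukin-35, was higher by 2.96 ± 0.35 (adjusted p = 1.5e-06), the inhibitory receptor gene Cd300lf by 2.23 ± 0.27 (adjusted p = 2.21e-06) and Il1a by 2.15 ± 0.28 (adjusted p = 6.91e-06), each in all 5 ears above all 13. The integrin of myeloid cells Itgam was higher at least 2.52-fold, the costimulator Cd80 at least 2.38-fold and P-selectin, Selp, by 1.60 ± 0.17. Nos2 (1.93 ± 0.25) and the hypoxia factor Hif1a (1.17 ± 0.25) were higher than the mean of the resistant groups, but did not pass against B6 L. major ears (0.18 and 0.76, adjusted p = 0.794 and 0.122), nor did Hif1a against BALB/c L. braziliensis ears (0.87, adjusted p = 0.0771). The cystathionine synthase gene Cbs was lower (-1.64 ± 0.22), in all 5 ears below all 13. Neither Ifng (-0.38 ± 0.19, adjusted p = 0.148) nor Il4 (0.85 ± 0.40, adjusted p = 0.122) passed. Ifng passed with median scaling (-0.60, adjusted p = 0.021) and with the mean of its probes (-0.55, adjusted p = 0.0118), and Il4 passed without BALB/c L. major replicate 5 (1.14, adjusted p = 0.0413). Both turned direction with slide as a block (0.13 and -0.34).

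Other genes of this comparison differed in the same direction between naive ears of the 2 strains. The cathepsin Ctsl was higher by 2.95 ± 0.21 here and by 2.14 ± 0.32 in naive BALB/c ears, and so were the urokinase gene Plau (at least 18.6-fold and 23.6-fold), the MHC gene H2-Q5 (2.84, and at least 8.18-fold), Serpina1d (at least 2.65-fold and 1.40-fold), the Fc receptor gene Fcgr3 (1.79 and 1.15) and the mast cell tryptase gene Tpsab1 (2.23 and 3.09). Lower in both were Arhgap12 (at least 4.41-fold, and -3.69), the T cell adaptor Trat1 (-2.08, and at least 6.84-fold), Avil (-2.01 and -1.76), Pamr1 (-1.72 and -1.38), the skin chemokine Ccl27a (-1.68 and -1.91), Calm4 of the epidermis (-1.59 and -1.59), Cd3g of the T cell receptor (-0.94 and -2.52) and the macrophage lectin Clec10a (-0.72 and -1.13).

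Limma passed 2573 genes, 1097 higher and 1476 lower, 525 of them at least 2-fold (304 higher, 221 lower). In 113 of them, and in 1.14% of all genes, the 5 ears lay beyond all 13 (by chance 0.0233%). Without the genes that differed between naive ears 2054 remained. Blocking by slide gave 1301, 781 of them shared with the 2573 in direction. With median scaling 17.4% of calls were higher rather than 42.6%, and the median gene moved from -0.05 to -0.22.

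Of 21 interleukin-1 list genes 17 were higher, 17 adjusted over the list alone (adjusted p = 6.55e-11, adjusted p = 0.397 with an estimated correlation), and with slide as a block 1 was and the list still passed (adjusted p = 0.0195). Il1b was higher by 2.25 ± 0.36 and by 1.14 with slide as a block (adjusted p = 0.202), and Cxcl2 by 3.68 ± 0.63 and by 1.63 (adjusted p = 0.303). Of 21 neutrophil genes 15 were higher, 17 adjusted over the list alone (adjusted p = 1.6e-09, adjusted p = 0.397 with an estimated correlation), and with slide as a block 4 were and the list did not pass (adjusted p = 0.0658). There the activating receptor Trem1 was higher by 2.87 ± 0.60 (0.78 with slide as a block, adjusted p = 0.618) and the chemokine receptor Cxcr2 by 2.60 ± 0.50 (1.49, adjusted p = 0.273). Of 30 wound and stress keratinocyte genes 17 were higher, 21 adjusted over the list alone (adjusted p = 4.27e-07, adjusted p = 0.58 with an estimated correlation), which slide as a block also ended (adjusted p = 0.0604). Slpi, a protease inhibitor of wounded skin, was higher by 2.26 ± 0.35 (1.11 with slide as a block, adjusted p = 0.207). Of 17 matrix metalloproteinases and inhibitors 12 were higher and 3 lower, the same adjusted over the list alone (adjusted p = 1.61e-05, adjusted p = 0.397 with an estimated correlation, and 0.127 with slide as a block). Of 25 hypoxia and glycolysis genes 9 were higher, 10 adjusted over the list alone (adjusted p = 1.51e-05, adjusted p = 0.397 with an estimated correlation, and 0.236 with slide as a block). The monocyte receptor Cd14 (2.38 ± 0.35), Inhba (2.91 ± 0.40) and Arg1 (1.86 ± 0.38) were likewise higher and did not pass with slide as a block (1.20, 1.48 and 0.94, adjusted p = 0.16, 0.125 and 0.368). Against BALB/c L. braziliensis ears alone Il1b, Trem1, Cxcr2 and Arg1 did not pass (adjusted p = 0.0991, 0.0978, 0.197 and 0.27).

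The same parasite in the 2 strains was compared directly, 5 BALB/c against 4 B6 ears with L. major. Several of the largest differences were present in naive ears too. H2-Ea, the MHC class II alpha chain that B6 mice do not express, was at least 528-fold higher in BALB/c (adjusted p = 7.81e-24), Plau at least 70.5-fold (adjusted p = 5.26e-15) and Tmem87a at least 33.4-fold (adjusted p = 4.64e-20), and Cap1 was higher by 5.74 ± 0.44. The alcohol dehydrogenase gene Adh7 was at least 135-fold lower in BALB/c (adjusted p = 1.43e-23), and Skint9 of the epidermis at least 61.4-fold lower (adjusted p = 1.04e-19). Klra7, not above background in naive ears of either strain, was at least 20.9-fold lower (adjusted p = 1.04e-19). Log2 values were -7.66 ± 0.22 for the Fc receptor chain Fcer1g, -5.14 ± 0.15 for the immunoproteasome subunit Psmb9 and -2.56 ± 0.26 for Trat1.

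Among genes that did not pass between naive ears, Il12a was higher in BALB/c by 2.64 ± 0.44 (adjusted p = 0.00016), Selp by 1.91 ± 0.22 (adjusted p = 1.08e-06) and the muscle gene Sln by 2.09 ± 0.37. The macrophage lysosomal gene Gpnmb was lower (-1.37 ± 0.21, adjusted p = 4.02e-05). Fcgr3 (1.70 ± 0.20), Tpsab1 (3.52 ± 0.27) and C1qb (-1.29 ± 0.15) differed in naive ears too. All 5 BALB/c ears lay beyond all 4 B6 ears for these genes and for Ifng, which was lower (-0.94 ± 0.24, adjusted p = 0.0112). Il1b was higher by 1.92 ± 0.45 (adjusted p = 0.00512), and Nos2 did not pass (0.18 ± 0.32, adjusted p = 0.794).

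Limma passed 1342 genes, 595 higher and 747 lower in BALB/c, 581 of them at least 2-fold. In 879 of them, and in 10.4% of all genes, the groups did not overlap (by chance 1.59%). Of the 805 genes that passed between naive ears 542 passed here, 5 of them in the opposite direction, and 800 calls remained without them. Blocking by slide gave 1283, 620 of them shared with the 1342 in direction. The blocked values compare 3 BALB/c ears with 1 B6 ear on slide 2 and decide nothing. By them Il12a was at 1.53, Il1b at 0.54 and Ifng at -0.34. With median scaling 20.6% of calls were higher rather than 44.3%, and the median gene moved from -0.01 to -0.19.

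Of 21 interleukin-1 list genes 14 were higher in BALB/c and 1 lower, 16 and 1 adjusted over the list alone (adjusted p = 2.06e-06). Of 21 neutrophil genes 6 were higher, 10 adjusted over the list alone (adjusted p = 0.00014). Of 25 interferon-gamma-inducible genes 7 were lower, 12 adjusted over the list alone, 12 without background correction and 11 with median scaling (adjusted p = 0.000166). With slide as a block these 3 lists did not pass. Of 17 T cell genes 7 were lower, 7 adjusted over the list alone (adjusted p = 0.00118). With an estimated correlation the adjusted p of these lists was 0.404, 0.454, 0.404 and 0.479. The interferon-gamma and T cell lists were lower in naive BALB/c ears too (mean -0.60 and -1.25, against -0.57 each with L. major).

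The parasites were compared within BALB/c mice, 5 ears with L. major against 4 with L. braziliensis. Nos2 was higher with L. major by 2.88 ± 0.32 (adjusted p = 5.39e-05), Clec4e by 2.44 ± 0.20 (adjusted p = 5.9e-07), Inhba by 2.54 ± 0.51, Slpi by 2.44 ± 0.45, Il12a by 2.38 ± 0.44 and the B cell receptor inhibitor Cd22 at least 1.92-fold. Il7r, the interleukin-7 receptor, was higher by 1.68 ± 0.33, Itgam by 1.49 ± 0.27, the angiogenic factor Vegfa by 1.19 ± 0.23 and Cd274 by 0.97 ± 0.19. Lower were the lymphocyte receptor Klrg1 (-1.68 ± 0.35), Cbs (-1.61 ± 0.28), the mast cell protease Mcpt4 (-0.99 ± 0.22), the nerve growth factor receptor Ngfr (-0.77 ± 0.16) and the defensin Defb6 (-0.76 ± 0.16). All 5 ears lay beyond the other 4 for these genes except Mcpt4. Il4 (-0.53 ± 0.51, adjusted p = 0.514), Arg1 (0.83 ± 0.49, adjusted p = 0.27) and Ifng (-0.22 ± 0.24, adjusted p = 0.59) did not pass.

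Limma passed 1123 genes, 491 higher and 632 lower with L. major, 195 of them at least 2-fold (155 higher, 40 lower). In 689 of them, and in 11.4% of all genes, the groups did not overlap (by chance 1.59%). A fit of only the groups compared passed 129 higher and 58 lower. Blocking by slide gave 349, 298 of them shared with the 1123. Within slide 2, 3 ears against 4, limma passed 0, with 1739 at unadjusted p under 0.05, and all 1123 had the same direction. There the genes named above as different had adjusted p between 0.0579 and 0.187. The count was 392, 519 and 629 without BALB/c L. braziliensis replicates 3, 4 and 1. It was 474, 549 and 1750 without BALB/c L. major replicates 1, 2 and 5. Scaled to a common median, 25.2% of calls were higher rather than 43.7%, and the median gene moved from -0.06 to -0.15.

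Among 21 interleukin-1 list genes 5 were higher with L. major, 10 adjusted over the list alone (adjusted p = 1.72e-06), of 21 neutrophil genes 4, 5 adjusted over the list alone (adjusted p = 1.06e-06), and of 25 hypoxia and glycolysis genes 7, 8 adjusted over the list alone (adjusted p = 6.49e-06). Of 12 mast cell, basophil and eosinophil genes 4 were lower, 5 adjusted over the list alone (adjusted p = 0.000697). Of 29 cell cycle genes 7 were lower, 8 adjusted over the list alone (adjusted p = 0.00159). With an estimated correlation the adjusted p was 0.347, and 0.562 for cell cycle genes. With the preset correlation all 5 lists passed with slide as a block (adjusted p 1.44e-05 to 0.000373) and within slide 2 (6.76e-06 to 0.00116). There the interleukin-1 score did not pass (exact permutation p = 0.343).

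The same question in B6 mice set 4 ears with L. major against 5 with L. braziliensis. Clec4e was higher with L. major by 2.68 ± 0.20 (adjusted p = 1.04e-07), Nos2 by 2.56 ± 0.32 (adjusted p = 0.000118), the cystine transporter gene Slc7a11 by 2.25 ± 0.40, the beta-glucan receptor Clec7a by 2.13 ± 0.35, Cd14 by 2.09 ± 0.44, Fpr2 by 2.05 ± 0.25, Saa3 by 1.64 ± 0.29, Isg15 by 1.60 ± 0.34, Il10 by 1.73 ± 0.40 and Tnf by 1.33 ± 0.30. In the epidermis Krt6b (3.05 ± 0.64), Rptn (2.17 ± 0.45) and Krt1 (1.59 ± 0.29) were higher. Cd22 (1.30 ± 0.28), the lectin Clec4n (1.34 ± 0.29), Hk3 (1.46 ± 0.20), the integrin chain Itgb2 (1.14 ± 0.24), Cst7 (0.95 ± 0.21) and Icam1 (0.89 ± 0.14) were higher as well. Lower with L. major were the muscle genes Actn3 (-2.15 ± 0.42), Sln (-2.14 ± 0.37) and Mybpc2 (-2.05 ± 0.44), as were the phosphatase gene Dusp26 (-2.04 ± 0.34), Cidec (-1.51 ± 0.28), Ucma (-1.39 ± 0.29), Fap (-1.26 ± 0.28) and Timp3 (-0.90 ± 0.21). The 4 ears lay beyond the other 5 for these genes except Krt6b and Cidec.

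Limma passed 1345 genes, 633 higher and 712 lower with L. major, 356 of them at least 2-fold. In 863 of them, and in 12.6% of all genes, the groups did not overlap (by chance 1.59%). A slide block gave 1716, 1092 of them shared with the 1345, and within slide 3, 3 ears against 5, 975 passed, with all 1345 in the same direction. The count was 417 without B6 L. major replicate 3 and 832 without B6 L. braziliensis replicate 5. Scaled to a common median, 35.8% of calls were higher rather than 47.1%, and the median gene moved from -0.04 to -0.11. The parasite comparisons of the 2 strains shared 210 higher and 83 lower genes (31.3 and 45.3 expected) and 9 of opposite direction, and they share no array.

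Of 25 interferon-gamma-inducible genes 17 were higher with L. major, 22 adjusted over the list alone (adjusted p = 6.55e-16), of 29 monocyte and macrophage genes 17, 20 adjusted over the list alone (adjusted p = 6.55e-16), and of 21 dendritic cell and MHC class II genes 6, with 7 higher and 1 lower adjusted over the list alone (adjusted p = 6.21e-06). Of 21 type I interferon-inducible genes 12 were higher, 18 adjusted over the list alone (adjusted p = 2.73e-13). Among 33 skeletal muscle genes 26 were lower, 31 adjusted over the list alone (adjusted p = 6.55e-16). Of 15 cartilage genes 9 were lower, 11 adjusted over the list alone (adjusted p = 1.37e-06). The latter had adjusted p = 0.0604, 0.237 and 0.221 with an estimated correlation. With the preset correlation the 6 lists passed within slide 3 (adjusted p 7.22e-17 to 1.6e-05) and blocked by slide (9.61e-18 to 2.08e-05).

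**Figure D3:**
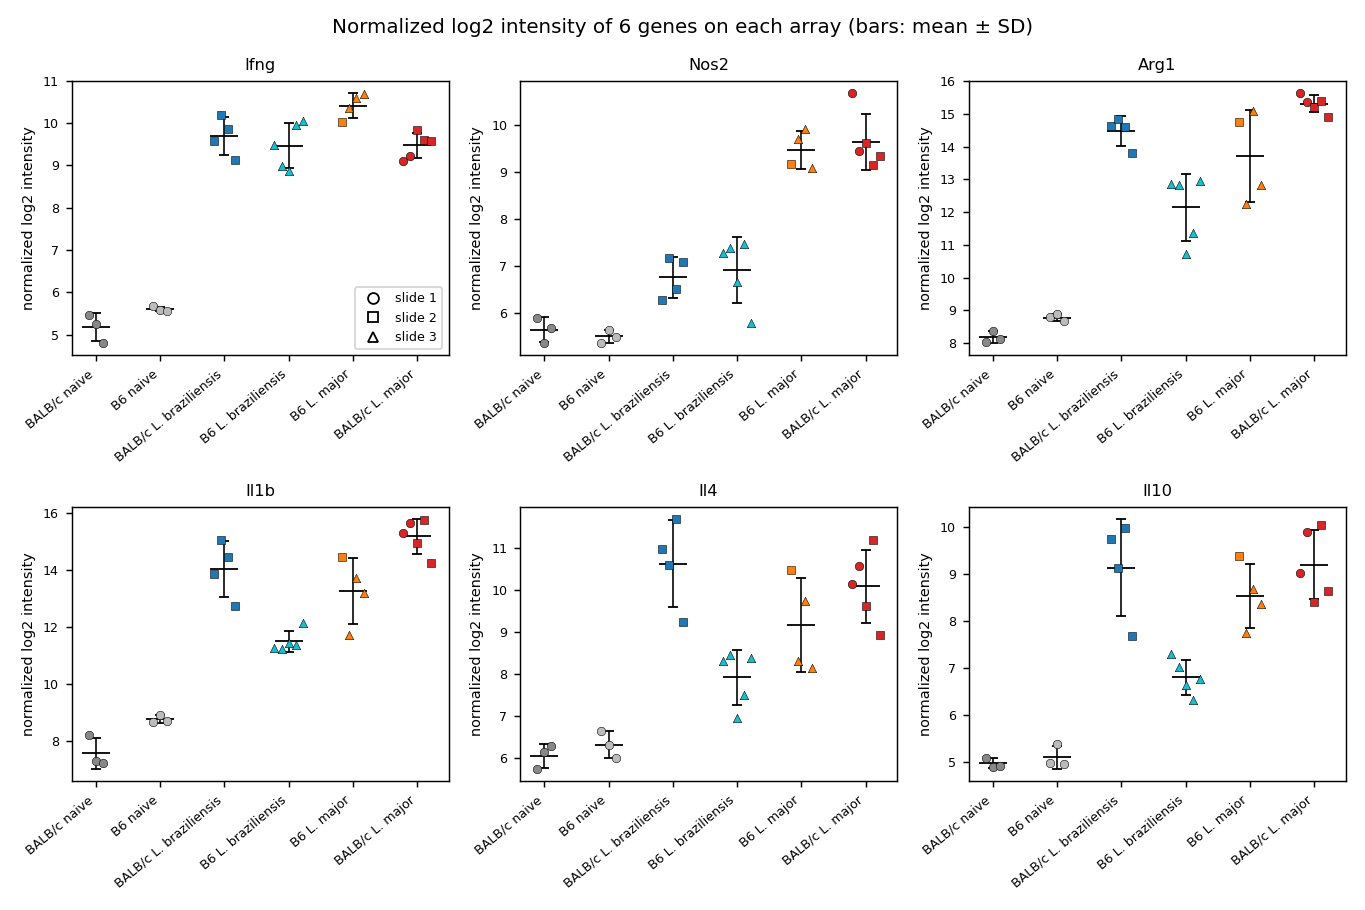
Normalized log2 intensity of 6 genes on each array by group, each point an array shaped by slide and each bar the group mean with its SD. Nos2 averages 9.64 and 9.47 in the BALB/c and B6 ears with L. major against 6.76 and 6.91 in those with L. braziliensis. Of the latter, 2 BALB/c and 3 B6 arrays detected it. Ifng averages between 9.47 and 10.4 in the 4 infected groups.

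With L. braziliensis, 4 BALB/c ears were set against 5 B6 ears. H2-Ea was at least 524-fold higher in BALB/c (adjusted p = 8.99e-24), Plau at least 65.7-fold (adjusted p = 2.62e-15) and Tpsab1 by 4.27 ± 0.27, and Fcgr3 was higher by 2.13 ± 0.20 and Tyrp1 by 1.54 ± 0.27. Adh7 was at least 174-fold lower (adjusted p = 8.99e-24) and Skint9 at least 64.9-fold lower (adjusted p = 6.57e-20), with Fcer1g at -7.45 ± 0.22 and Psmb9 at -4.72 ± 0.15. The protease gene Adamts4 was at least 7.67-fold higher (adjusted p = 3.81e-06), the interferon-induced Mx2 by 1.73 ± 0.21 and Gbp4 by 1.03 ± 0.18, the transglutaminase Tgm3 of hair and epidermis by 1.25 ± 0.22 and Top2a by 1.09 ± 0.18.

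Higher in BALB/c on all 4 arrays were Il4 by 2.70 ± 0.51 (adjusted p = 0.000443), Il10 by 2.32 ± 0.40 (adjusted p = 0.000183), Il1b by 2.54 ± 0.45 (adjusted p = 0.000254) and the neutrophil chemokine Cxcl5 by 3.57 ± 0.70. Arg1 was higher by 2.33 ± 0.49, Foxp3 by 1.00 ± 0.19 and the granzyme Gzma by 2.12 ± 0.40, and Myh1 was lower (-2.08 ± 0.41). Blocked by slide, these 8 genes did not pass, at 0.97 for Il4, 1.19 for Il10, 0.97 for Il1b, 0.75 for Cxcl5, 0.98 for Arg1, 0.56 for Foxp3, 1.23 for Gzma and -0.79 for Myh1 (adjusted p between 0.308 and 0.713).

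Limma passed 3036 genes, 1467 higher and 1569 lower in BALB/c, 913 of them at least 2-fold. In 2303 of them, and in 27.3% of all genes, the groups did not overlap (by chance 1.59%). Of the 805 genes that passed between naive ears 576 passed here, 15 of them in the opposite direction, and 2460 calls remained without them. A slide block gave 1378, 759 of them shared with the 3036 in direction, and no slide holds both groups. Scaled to a common median, 25.8% of calls were higher rather than 48.3%, and the median gene moved from 0.02 to -0.13.

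Of 21 hair follicle genes 11 were higher in BALB/c, 12 adjusted over the list alone (adjusted p = 6.93e-06). Among 21 interleukin-1 list genes 15 were higher, 15 adjusted over the list alone (adjusted p = 6.23e-05). Of 12 mast cell, basophil and eosinophil genes 7 were higher, 7 adjusted over the list alone (adjusted p = 0.00209). Among 33 skeletal muscle genes 17 were lower, 19 adjusted over the list alone (adjusted p = 6.93e-06). With slide as a block the adjusted p was 0.00858, 0.405, 0.0543 and 0.204 in this order. With an estimated correlation it was 0.795 for each list but 0.828 for muscle genes.

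The baseline was the comparison of 3 naive BALB/c with 3 naive B6 ears, all on slide 1. H2-Ea was at least 267-fold higher in BALB/c (adjusted p = 3.22e-21), Tmem87a at least 37.8-fold, Plau at least 23.6-fold, the RNA-binding gene Rbm45 at least 13.6-fold, Mpo at least 4.88-fold and the beta-globin gene Hbb-b2 at least 3.52-fold, and Cap1 was higher by 4.59 ± 0.54, Tpsab1 by 3.09 ± 0.33, Ctsl by 2.14 ± 0.32 and Fcgr3 by 1.15 ± 0.25. Adh7 (Entrez 11529, chromosome 3) was at least 264-fold lower (adjusted p = 4.7e-22), Skint9 at least 90.4-fold, Fcer1g at least 54.3-fold, Thumpd1 at least 36.2-fold, Pdrg1 at least 31-fold and Psmb9 at least 12.2-fold, and the log2 value of the serpin gene Serpina12 was -6.69 ± 0.34. Among lymphocyte genes Trat1 was at least 6.84-fold, the costimulator Tnfrsf4 at least 6.66-fold and the chemokine Xcl1 at least 5.82-fold lower in BALB/c, with Cd3d at -2.85 ± 0.30, Nkg7 at -2.76 ± 0.33 and the epidermal homing integrin Itgae at -1.72 ± 0.22. H2-Aa of MHC class II was at -2.71 ± 0.28, and the neutrophil genes S100a8 and Stfa1 at -3.20 ± 0.68 and -3.70 ± 0.74. All 3 ears lay beyond the other 3 for every gene named in this comparison.

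Limma passed 805 genes, 298 higher and 507 lower in BALB/c, 481 of them at least 2-fold. In 802 of them, and in 31.8% of all genes, the groups did not overlap (by chance 10%). Slide as a block gave 1073, with all 805 among them, and a fit of slide 1 alone 1158. Under median scaling 49.5% of calls were higher rather than 37%, and the median gene moved from 0.01 to 0.12.

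Of 17 T cell genes 9 were lower in BALB/c and 1 higher, the same adjusted over the list alone (adjusted p = 2.67e-09), and of 16 cytotoxic lymphocyte genes 5 were lower, 7 adjusted over the list alone (adjusted p = 1.72e-05). Of 4 erythrocyte genes 2 were higher, 4 adjusted over the list alone (adjusted p = 0.0009). These 3 lists had adjusted p = 0.252 with an estimated correlation. Of 7 melanocyte genes 4 were higher, 4 adjusted over the list alone (adjusted p = 0.00385, adjusted p = 0.322 with an estimated correlation). Each passed within slide 1 (adjusted p between 2.77e-07 and 0.00606).

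Whether infection changed a gene differently in the 2 strains was tested by the interaction of strain and infection, BALB/c change minus B6 change. For L. major 59 genes passed, 40 higher and 19 lower. Xcl1 rose at least 2.96-fold more in BALB/c (adjusted p = 0.000108), and so did the natural killer receptor Klrd1 (by 2.40 ± 0.38) and S100a8 (by 4.86 ± 0.88, adjusted p = 0.00679). S100a8 did not pass with slide as a block (3.32, adjusted p = 0.149). Klra7 and Klra4, receptors of the Ly49 cluster whose gene content differs between strains, and the receptor Cd300ld rose in B6 and passed (adjusted p = 1.81e-14, 5.21e-07 and 1.04e-05), but were not above background in any BALB/c ear. Among 21 interleukin-1 list genes 3 were higher, 13 adjusted over the list alone and 5 with median scaling (adjusted p = 6.67e-13, adjusted p = 0.424 with an estimated correlation, and 0.0428 with slide as a block). A slide block gave 78 genes, 18 of them among the 59. The count was 154 without B6 L. major replicate 1 and 111 without BALB/c L. major replicate 5. It was 37 and 36 without BALB/c naive replicates 2 and 3, and 35 without B6 naive replicate 1 or 3. Under median scaling 29.2% of calls were higher rather than 67.8%, and the median gene moved from -0.03 to -0.33.

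For L. braziliensis 349 genes passed, 175 higher and 174 lower. Xcl1 (at least 2.97-fold, adjusted p = 0.000105) and Nkg7 (3.07 ± 0.42, adjusted p = 0.000567) rose more in BALB/c, as did Ccl4 (at least 13.2-fold, adjusted p = 0.00475) and Il1b (3.74 ± 0.71, adjusted p = 0.00775), which did not pass with slide as a block (2.70 and 2.17, adjusted p = 0.174 and 0.225). Of 17 T cell genes 8 rose more in BALB/c, 10 with 1 the other way adjusted over the list alone (adjusted p = 8.36e-09). Among 21 interleukin-1 list genes 6 did, 12 adjusted over the list alone and 2 without background correction (adjusted p = 6.24e-09). Both lists had adjusted p = 0.278 with an estimated correlation. The T cell score averaged -1.88 in naive and 0.29 in infected BALB/c ears, against -0.63 and 0.43 in B6 ears. Among 33 skeletal muscle genes 7 fell more in BALB/c, 25 adjusted over the list alone and 17 with median scaling (adjusted p = 6.03e-15, adjusted p = 0.309 with an estimated correlation). The 3 lists passed with slide as a block (adjusted p = 3.59e-05, 0.0135 and 1.36e-05). Blocked by slide, 179 genes passed, 40 of them among the 349. The count was 130, 149, 157 and 664 without BALB/c L. braziliensis replicates 1 to 4. It was 183, 184 and 191 without B6 replicates 3 to 5. Without naive replicates 1 to 3 it was 82, 165 and 204 for B6 and 189, 115 and 114 for BALB/c. Under median scaling 15.8% of calls were higher rather than 50.1%, and the median gene moved from 0.00 to -0.26.

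The interaction of strain and parasite asked whether L. major and L. braziliensis differed more in BALB/c than in B6, and 63 genes passed, 39 higher and 24 lower. The muscle genes Myh1 (2.61 ± 0.58, adjusted p = 0.0428) and Mb (2.26 ± 0.50, adjusted p = 0.0428) were lower with L. major in B6 and not in BALB/c, and the death ligand Fasl (-1.49 ± 0.32, adjusted p = 0.0399) and Gbp4 (-1.39 ± 0.26, adjusted p = 0.0399) had the opposite sign. Among 33 skeletal muscle genes 2 passed, 26 adjusted over the list alone, 6 without background correction and 4 with median scaling (adjusted p = 9.79e-21, adjusted p = 0.442 with an estimated correlation, and 4.13e-30 with slide as a block). Leaving out 1 array ended many of these calls. The count was 123, 4, 2, 1 and 10 without B6 L. braziliensis replicates 1 to 5, 34, 225, 1 and 1 without B6 L. major replicates 1 to 4, 5, 23, 1 and 180 without BALB/c L. braziliensis replicates 1 to 4, and 40 and 2 without BALB/c L. major replicates 1 and 2. Over the same runs the adjusted p reached 0.107 for Myh1 and for Mb, 0.0972 for Fasl and 0.0734 for Gbp4. Blocked by slide, 250 genes passed, 46 of them among the 63.

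The genes shared by the 2 contrasts that single out the susceptible mice were counted, BALB/c against B6 with L. major and L. major against L. braziliensis in BALB/c. They shared 89 higher and 110 lower genes (29.4 and 47.5 expected) and 45 of opposite direction, and 69 and 83 of the shared genes had not passed between naive ears. Il12a, Selp, Slpi and Itgam were among the higher ones and Cbs among the lower. When the 5 BALB/c L. major ears that both contrasts use were split between them in the 20 ways of 2 and 3, a median of 21.5 genes were higher in both (6.37 expected, range 0 to 69) and 18.5 lower in both (9.48 expected, range 0 to 89), with 12.5 of opposite direction. The covariance of the contrasts was 0.0631 with all 5 ears, 0.0409 with split ears and 0.0231 in simulations without change, and the correlation 0.236, 0.145 and 0.445.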

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

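The 9 tests of the patterns weighed here were chosen only after the results were seen, and the tests by other splits of the arrays before.

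In 68 groups of values tested for a single far value, 4 were found, and chance finds about 1 in 20. The median signal before normalization of B6 L. major replicate 1 was 302.5, against 432.7 to 443 in its group (gap over range 0.927), and that array alone of its group lay on slide 2. Il1b in B6 L. braziliensis replicate 5 was 12.15, against 11.24 to 11.42 (0.801). Tnf in BALB/c L. braziliensis replicate 4 was 9.01, against 10.29 to 10.54 (0.838). Retnla in B6 L. major replicate 4 was 8.00, against 10.65 to 11.01 (0.88).

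By interaction the strains differed in 59 genes for L. major, 349 for L. braziliensis and 63 for the parasite contrast. For L. major these included Il1b (3.12, adjusted p = 0.0451) and S100a8 (4.86), and for L. braziliensis Il4 (2.96), Il10 (2.45), Arg1 (2.93), Il1b (3.74), Tnf (1.79), Cxcl9 (2.02) and Foxp3 (1.42), each fitted as rising more in BALB/c. Il4 and Il10 were not above background in naive ears, nor Tnf and Cxcl9 in naive BALB/c ears. At the floor the latter are at least 1.56 and 1.07. With L. braziliensis Cxcl9 averaged 14.28 in BALB/c and 14.75 in B6 ears. With slide as a block only Cxcl9 of these passed, and it did not without background correction (0.46, adjusted p = 0.5). Leaving out 1 array ended the call of Il1b for L. major in 12 of 15 runs (adjusted p up to 0.145), of Il4 in 12, Il10 in 12, Arg1 in 11 and Tnf in 13 (up to 0.115, 0.0892, 0.0942 and 0.0968), and of Foxp3 in 1, without B6 naive replicate 1 (0.0547).

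Probes without a gene name changed too, 356, 330, 288 and 115 of 831, in BALB/c L. major, B6 L. major, BALB/c L. braziliensis and B6 L. braziliensis ears against naive ones.

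Other splits of the arrays test whether chance can give as many genes. It can be excluded for BALB/c L. major (4998, highest other split 3678), B6 L. major (4280, 3241), BALB/c L. braziliensis (4063, 3374) and B6 L. braziliensis ears (1689, 249) against naive ones, each with 1 split as large, the real one. The same holds, in 100 splits drawn, for the parasites in B6 (1345, 721). It holds for susceptible against resistant mice (2573, 487) and L. braziliensis between strains (3036, 1808). Splits do not test the overlap of 4 infections (1094, 0). Naive ears had too few splits, 10 (805, 0). Of 100 splits 6 gave as many for the L. major interaction (59, highest 1100) and 5 for the parasite one (63, 722). For the L. braziliensis interaction only the real split did (349, 267). What gave the highest counts was not tested, so chance is not excluded for any interaction. For L. major between strains 1 of 100 splits drawn from 126 was as large, the real one (1342, highest other drawn 1239). The split by slide, ears of slide 2 against the others, was not drawn and called more (1556), so slide is not excluded there. Fits by slide rest there on 1 B6 array. For L. braziliensis between strains and against naive ears the real split is also one of slides, so slide is not excluded there.

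Among the 170 genes that differed at least 4-fold between naive strains, 28 had other detected probes, and 17 of those 37 probes moved at least 0.5 times as far. For genes that changed as much with L. major in BALB/c it was 133 of 170 probes (Fisher's exact p = 0.000175, 2-sided). A sequence difference under the probe may therefore make up part of the strain differences. A difference in expression stays open for the rest, among them H2-Ea.

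The interleukin-1 score of susceptible ears was higher than in B6 L. major ears by 1.45 (5 against 4, exact permutation p = 0.0317) and B6 L. braziliensis ears by 2.42 (5 against 5, exact p = 0.00794), and differed from BALB/c L. braziliensis ears by 0.91 (5 against 4, exact p = 0.0873). More leukocytes of every kind would raise macrophage genes as much, but the score minus the macrophage score was higher than in B6 ears, by 1.70 and 1.84 (exact permutation p = 0.0159 and 0.00794), while the difference from BALB/c L. braziliensis ears, 0.51 (exact p = 0.159), leaves this open between the parasites. A larger share of neutrophils stays open, since 15 of 21 neutrophil genes were higher than in the resistant groups. The strain's baseline lay the other way (-0.46 between 3 and 3 naive ears, exact permutation p = 0.1, the smallest possible). Slide cannot be told apart, since within slide 2 the score differed from BALB/c L. braziliensis ears by 0.68 (3 against 4, exact permutation p = 0.343) and from the 1 B6 L. major ear by 0.29.

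The muscle score was lower in B6 ears with L. major than with L. braziliensis by a difference of -1.39 (4 against 5, exact permutation p = 0.0238). Dilution of all resident transcripts alike would lower every resident score as much. The muscle score minus the keratinocyte differentiation score differed by -1.40 (exact permutation p = 0.0397). Endothelial, melanocyte, collagen and hair follicle scores were not clearly lower (-0.02 to 0.44). These values argue against dilution of all alike. Cartilage, adipocyte, nerve and sebaceous scores were lower too (-0.83 to -0.40), so a fall shared by some resident tissues stays open. Within slide 3 the muscle score still differed by -1.26 (3 against 5), which argues against slide but does not exclude it (exact permutation p = 0.0536). Of 33 muscle genes 13 were lower there, against 4.67% of the others, and over all slides 26 were, with and without slide as a block. For the muscle genes of B6 L. braziliensis ears, near naive level, slide cannot be told apart, since no slide holds both groups and 12 were lower with slide as a block. A loss of muscle beneath the lesion, or a different share of muscle in the sampled ear, could each give this and neither was tested.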

How the results depend on the processing

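Tests chosen only after the results were seen are those without genes that differed between naive strains, with BALB/c L. major arrays of slide 2 only, of lists within slides, and of lists with median scaling. Over all settings 6459 of 6673 values of named genes kept direction and side of the threshold, 205 lost the call, 3 gained it and 6 turned. For lists, run in fewer settings and without leaving out arrays, these were 559, 80, 19 and 4 of 662. Unless a setting's construction shows it (a stricter threshold, fewer arrays or genes), the cause was not tested. Signal over background limits genes not detected in a group, which have only a bound.

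In the order used here (BALB/c L. major, B6 L. major, BALB/c L. braziliensis and B6 L. braziliensis against naive, L. major between strains, the parasites in BALB/c, susceptible against resistant, the parasites in B6, L. braziliensis between strains, naive strains) at least 2-fold change left 2022, 1658, 1634, 593, 581, 195, 525, 356, 913 and 481 genes, with 38 for the parasite interaction and 418 shared by 4 infections. At adjusted p under 0.01, from B6 L. major on, 2828, 2691, 841, 789, 246, 1441, 363, 1712 and 512 passed, with 27, 48 and 1 for the L. major, L. braziliensis and parasite interactions and 591 shared by 4 infections.

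Slide as a fixed block gave 349 for the parasites in BALB/c, 1301 for susceptible mice, 1378 for L. braziliensis between strains, and 179 and 250 for the L. braziliensis and parasite interactions. As a random block it gave 876 for L. major between strains, 548, 1325 and 1011 for those 3 comparisons, and 26, 38 and 179 for the 3 interactions. Slide 2 alone, with 1 B6 array, gave 876 for L. major between strains and 0 for the parasites in BALB/c (limma, 1739 at unadjusted p under 0.05). BALB/c L. major arrays of slide 2 only gave 224 there and 216 for the parasite interaction. Only the groups compared gave 758 for L. major between strains, 187 for the parasites in BALB/c, 797 in B6, 1127 for the L. braziliensis interaction and 0 for the parasite interaction (limma). Array weights gave 3267 for B6 L. braziliensis, 1814 for naive strains, and 509, 2166 and 226 for the interactions. Median scaling gave 3915 for susceptible mice, and 195 and 913 for the first 2 interactions. The L. braziliensis interaction had 229 without a filter. The parasite interaction had 11 without a filter, 164 without background correction, 163 with the series matrix and 101 with a trended, robust variance. Without genes that differed between naive strains, L. major between strains had 800. Replicate numbers do not pair arrays (mean correlation of residuals 0.0148 for same numbers, -0.00409 for others), and as a block they gave 18 for the parasite interaction and adjusted p = 0.0554 for ribosomal genes in BALB/c L. major ears.

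Leaving out each array in turn gave 4149 to 5093, 3326 to 4300, 3217 to 4198, 942 to 1770, 1039 to 1714, 392 to 1750, 1831 to 2960, 417 to 1550, 2196 to 3156 and 585 to 688 genes in the order above, 35 to 154, 82 to 664 and 1 to 225 for the interactions, and 680 to 1227 shared by 4 infections.

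Nos2 between strains with L. major turned to -0.075 with median scaling, -0.082 without BALB/c L. major replicate 1 (leaving out 1 array gave -0.082 to 0.32) and -0.10 with BALB/c arrays of slide 2 only against all B6 arrays. In susceptible mice Ifng turned to 0.13 and Il4 to -0.34 with slide as a block, and Prf1 in B6 L. braziliensis ears to 0.28 with the mean of its probes. Of lists that did not pass, hair follicle genes turned by fry (adjusted p = 0.871) and without a filter (0.912), sex-linked markers with slide as a block (0.982) and keratinocyte differentiation with median scaling (0.531), all in BALB/c L. major against naive ears.

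With an estimated correlation 57 of 87 list results lost the call. In BALB/c L. major against naive ears the adjusted p was 0.19 for alternatively activated macrophage, cartilage, mitochondrial and melanocyte genes, 0.0606 neutrophil, 0.0857 B cell, 0.208 wound keratinocyte, 0.292 sebaceous, 0.269 adipocyte and ribosomal, 0.405 muscle, 0.196 metalloproteinase, 0.409 cell cycle, 0.177 hypoxia and 0.295 nerve genes. It was 0.235, 0.198, 0.408, 0.408 and 0.313 in B6 L. major, 0.134, 0.0789, 0.267, 0.139 and 0.305 in BALB/c L. braziliensis, 0.27 in B6 L. braziliensis, 0.397 and 0.58 in susceptible mice, 0.404, 0.454 and 0.479 for L. major between strains, 0.347 and 0.562 for the parasites in BALB/c, 0.0604, 0.237 and 0.221 in B6, 0.795 and 0.828 for L. braziliensis between strains, 0.252 and 0.322 for naive strains, and 0.424, 0.278, 0.309 and 0.442 for interactions.

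For lists of BALB/c L. major against naive ears, type 2 genes passed by fry (0.000305), with slide as a block (0.041), on slide 1 (0.00299) and with median scaling (0.0298), and immediate early genes by these (0.00042, 0.0076, 0.00406, 0.0298) and without a filter (0.0373). Mast cell genes passed by fry (0.0227), on slide 1 (0.0403) and without a filter (0.0352), collagen genes by fry (0.00152) and without a filter (0.0243), endothelial genes by fry (0.0197) and on slide 1 (0.0458), and erythrocyte and sex-linked genes by fry (0.0213, 0.0243). Nerve genes did not pass with slide as a block (0.0506) or median scaling (0.0565), ribosomal genes with either (0.111, 0.887) or on slide 1 (0.158), and melanocyte genes on slide 1 (0.0514). Fry ended cell cycle genes for the parasites in BALB/c (0.0924), interleukin-1 genes in the L. major interaction (0.0852) and muscle genes in the parasite interaction (0.114). Slide as a block ended neutrophil (0.0658), wound (0.0604), metalloproteinase (0.127) and hypoxia genes (0.236) in susceptible mice, interleukin-1 and interferon-gamma (0.347 each) and neutrophil genes (0.709) for L. major between strains (0.414, 0.396 and 0.752 on slide 2), and interleukin-1 (0.405), mast cell (0.0543) and muscle genes (0.204) for L. braziliensis between strains. It made muscle genes pass in B6 L. braziliensis ears (4.84e-07).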

Other observations

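Nos2 averaged 9.64 ± 0.60 (normalized log2 intensity, SD, n = 5) in BALB/c ears with L. major, which the labels call susceptible, and 9.47 ± 0.40 (n = 4) in B6 ears with L. major. With L. braziliensis it averaged 6.76 ± 0.44 (n = 4) and 6.91 ± 0.71 (n = 5), and in naive ears 5.64 and 5.50, where 0 arrays detected it. Il17a, a cytokine that draws neutrophils, was below the detection filter, and the interleukin-12 subunit Il12b was not on the array by that name. Il13 and Retnla, genes of type 2 responses, did not pass in any of the 13 comparisons.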
